A study of Mus musculus and Homo sapiens with 60 samples.

How the data were processed

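Polyadenylated RNA was sequenced from cultured pancreatic islets, the clusters of endocrine cells that hold the insulin-producing beta cells. Per the labels' protocols, wild-type mouse islets and human donor islets received a 1 h pulse of 10 µM forskolin, an activator of adenylyl cyclase used to set the cells' clocks to a common phase, and were collected every 4 h from 40 h after the pulse. The mouse series holds 36 libraries, 3 at each of 12 time points. The human series holds 18 libraries, 3 donors at each of 6 time points. A further 3 libraries came from islets of mice lacking Bmal1 in the pancreas and 3 from floxed controls, isolated at ZT2, where ZT counts hours after lights on. No value of these 6 libraries was used, and the comparison of knockout and control is not analysed here.

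Per the submitters' processing notes, STAR and DESeq2 were used and the genome build was mm10; no versions are given, and the build of the human reads is not given in the sources used here. The authors deposited 1 table per species that lists only genes they had selected as cycling in these same libraries. For each gene the deposited table gives 1 normalized signal per time point, an average that the authors made over the libraries of that time point, with column heads counting hours since the pulse (CT40 to CT84 in the mouse, CT40 to CT60 in the human). Libraries could not be told apart in these columns, so no SD between replicates or donors exists in what follows and no library could be left out. Every p-value of a limma fit measures the scatter of time-point averages around fitted values. Those from random lists, permutations of genes and camera compare genes with each other, and they measure no spread between libraries either. The depth of the libraries is unknown. The deposited tables also give the p-values of the authors' rhythm test, with their adjusted forms, and scores per gene that the authors named period, phase, asymmetry, tau, maximum, minimum and fold change. In the values, the second p-value is the first multiplied by 30 in 3903 of 3905 mouse genes and in 1788 of 1800 human genes, to within 0.01 of the ratio, and it lies below 0.05 in every listed gene (highest 0.0487 and 0.0477). The ranks of the adjusted p-values imply that 14404 mouse and 15362 human genes were tested. The authors' maximum, minimum and fold change refer to standardised values and are not used here as expression levels. The highest human standardised value, 2.24, is the limit for 6 values standardised together, whereas the highest mouse value, 5.76, exceeds the limit of 3.32 for 12 values. Standardisation by donor in the human table and not by replicate in the mouse table would give these limits, but no source used here states the step.

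Identifiers made only of digits, 5 in the mouse and 2 in the human table, carried no values and were left out, and 1 more human row was dropped under a privacy rule. The 3900 mouse and 1797 human genes that remained were analysed. The design written before the data were examined assumed values per library; with averages, the same test was applied to the time-point values. Values were transformed as log2(value + 1), and a cosine with a period of 24 h was fitted with limma 3.58.1 in R 4.3.3 (variance trend, F test of 2 coefficients, Benjamini-Hochberg adjustment over the table, threshold 0.05). Amplitude, peak time and the fitted peak-to-trough fold on the log2(value + 1) scale, with 95% intervals, came from the same coefficients, with 9 residual degrees of freedom in the mouse and 3 in the human before moderation. Peak times are given modulo 24, so that CT40 and CT64 are both CT16. In the mouse, a second limma test asked whether the 6 times of day differed at all, with the 2 days as repeats. It had been planned as a test over single time points and was adapted after the data were seen. Day 2 (CT64 to CT84) was compared with day 1 (CT40 to CT60) at matched phase, with an interaction test for the rhythm, and with camera over the gene lists at a preset correlation of 0.01 and at an estimated correlation. In human samples peak times rest on 1 cycle, so a 24 h wave and a trend are partly the same.

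The 23 gene lists were fixed before the data were examined. For a list with at least 5 members, the resultant length R of its peak times (1 when all coincide) was set against 10000 random lists of the same size from the same table, one-sided, with Benjamini-Hochberg adjustment over lists. Genes of a list are not independent replicates, and members that move together give a high R whatever the source. The fixed rule counted members past the cosine threshold. In the mouse no list reached 5 such members, so all listed members entered, a choice made after the data were seen. Peak times were compared between species by symbol, ignoring case. The fixed rule, genes past the threshold in both tables, left 2 genes, so the genes listed in both tables were used instead. Their matching was permuted 100000 times, two-sided. Genes named in the text are every listed core clock member, the 10 largest amplitudes and 2 members per list. The fixed rule asked for calls of the cosine test and for the same timing in each replicate. In the mouse it gave only clock genes, so the largest amplitudes were taken from genes past the time-of-day test, with a mean level at or above the 25th percentile and the peaks of both days within 4 h of the pooled peak, and list members by the authors' p-values. A few genes that the rule takes are not reported here. Further members of a short list are named to complete its account, after their values were seen. Coordinates, genomic span, transcript length and GC come from GENCODE M21 on mm10, which matched 3876 of the 3900 mouse genes analysed (99.4%). Human genes took the span of the mouse gene of the same symbol, found for 81.7%. Members of large families with processed pseudogenes, ribosomal proteins among them, can share reads with those copies, and whether strand was used in counting is not stated.

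The fits were tested on simulated data with known answers. In the mouse layout 30% of 50 genes with a log2 amplitude of 0.2 were recovered, 84% at 0.4, 92% at 0.8 and 100% at 1.6, with 8 false calls among 3700 flat genes. In the human layout the shares were 42%, 84%, 98% and 100%, with 4 false calls among 1597. Noise was drawn independently for each gene. In the real mouse columns 1 component shared by the genes held 67.0% of the variance, so these counts of false calls need not hold there. The comparison of days recovered 196 of 200 genes changed by 1 log2 unit. The interaction test recovered 198 of 200 genes given a log2 amplitude of 1 on both days in opposite phase. Both changes are far larger than the median fitted mouse amplitude of 0.149, and smaller ones were not simulated for these tests. Alternatives covered the pseudocount (0.5 and 5), a table mean of at least 10, rescaling by median ratios, periods of 22 h and 26 h, a linear trend, ranks, and omission of each time point in turn. Rescaling factors lay between 0.952 and 1.03 in the mouse. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.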

Results

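Transcript levels were followed in cultured islets after a forskolin pulse, over 12 time points in wild-type C57BL/6 mouse islets and over 6 in human donor islets. The authors' deposited tables list 3905 mouse and 1800 human genes, selected by the authors as cycling, which is 27.1% and 11.7% of the 14404 and 15362 genes their adjusted p-values imply were tested. Every level given here is the authors' average of the libraries of a time point. Because the genes were chosen for cycling in these libraries, counts of rhythmic genes below are not independent evidence of cycling. Summed over listed genes, the columns held 6881311 to 7582120 normalized units in the mouse and 2553736 to 2680469 in the human, which is not a sequencing depth.

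The first question was which mouse transcripts followed a daily cycle. Among core clock genes, 4 did so by the cosine test, Arntl and Nfil3 peaking at one time of day and Dbp and Nr1d1 at another. Arntl (also Bmal1), the DNA-binding activator of the clock, rose to a fitted peak at 5.49 ± 0.45 h (SE of the fit) with a 1.86-fold peak-to-trough range (95% interval 1.59 to 2.18). Its average level was 251 at CT44 and 521 at CT52 on the first day, and 279 at CT64 and 536 at CT76 on the second. Dbp, a target of that activator, peaked at 15.4 ± 0.45 h with a 1.84-fold range (1.58 to 2.15), and Nr1d1 (Rev-erbα), a repressor of Arntl, peaked at 13.7 ± 0.53 h with a 1.83-fold range (1.53 to 2.19). Nfil3, a repressor that binds the same sites as Dbp, peaked at 4.80 ± 0.52 h with a 1.52-fold range (1.34 to 1.71). These 4 genes were the ones past the cosine test (limma, adjusted p = 0.00742 for Arntl and Dbp, 0.0222 for Nr1d1 and Nfil3). Of the 20 core clock genes of the fixed list, 14 were in the authors' deposited table, and 10 of these passed when adjusted over the list alone, a list already filtered for cycling.

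In mm10, Arntl spans 113207465 to 113314126 on chromosome 7, on the plus strand, and Dbp spans 45705088 to 45710203 on the same chromosome and strand. Nr1d1 lies on the minus strand of chromosome 11 (98767932 to 98775333) and Nfil3 on the minus strand of chromosome 13 (52967209 to 52981073). All are annotated as protein-coding genes, and the values refer to whole genes.

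**Figure D1:**
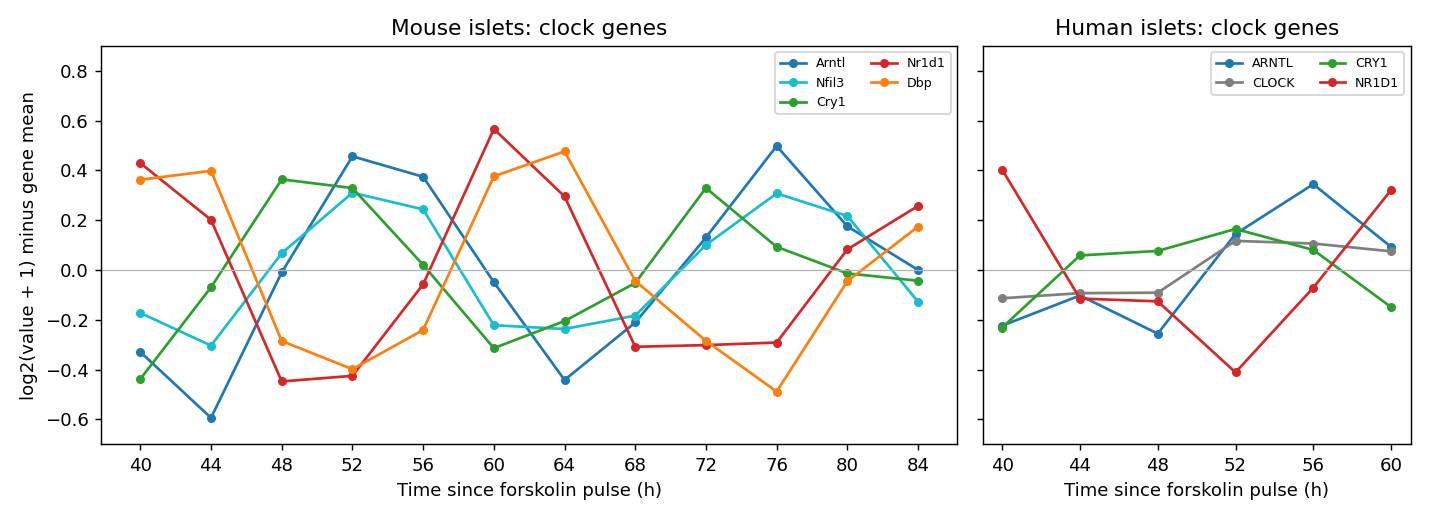
Authors' average level of each clock gene, as log2(value + 1) minus the gene's mean over its series (vertical axis), against hours since the forskolin pulse (horizontal axis), in mouse islets on the left and human islets on the right; each point is 1 time-point average, without error bars because single libraries were not used. Arntl and Nfil3 are high near CT52 and CT76, where Dbp and Nr1d1 are low.

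The other clock genes did not pass the cosine test over the table. Cry1, a core repressor, had a 1.53-fold range and a fitted peak at 2.28 h. It had an adjusted p of 0.0885 in the cosine test but differed among the 6 times of day (limma F test, adjusted p = 0.00442). Npas2 and Clock, partners of Arntl, had fitted peaks at 7.54 h and 7.28 h, Rora at 7.73 h, Nr1d2 at 14.8 h and Tef at 16.8 h. The period genes Per3 and Per2 had fitted peaks at 21.2 h and 23.6 h. Peaks of Rora, Per3 and Per2 come from weak fits (unadjusted p = 0.095, 0.271 and 0.119). In all, 13 of the 14 listed clock genes differed among times of day, Rorb being the exception (adjusted p = 0.192, mean level 10.6).

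Across the mouse table, the cosine test called 4 of 3900 genes (0.103%), with 1280 at an unadjusted p under 0.05, whereas 3045 (78.1%) differed among times of day. No gene passed the cosine test when CT64 or CT76 was left out. Adding a 12 h cosine to the 24 h cosine raised the count to 3192, and the 12 h term itself passed in 2323 genes. The authors' deposited table gives 2108 genes with an adjusted p below 0.05, adjusted over all genes they tested and so not comparable with these counts. Fitted peaks fell into separate windows of the day: 1659 genes (42.5%) peaked from CT14 to CT22 and 2006 (51.4%) from CT2 to CT10. The median fitted range was 1.23-fold. Mouse peak times below are those of the fitted 24 h cosine, which can differ from the time of the highest level.

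Genes for protein synthesis and respiration had their peaks in the first of these windows. All 70 listed cytosolic ribosomal protein genes, of 83 annotated, peaked between 15.7 h and 18.4 h, with a mean peak at 17.0 h (R = 0.987, adjusted p = 0.00047 against random lists), and all 70 differed among times of day, over the table and adjusted over the list alone. Rpl24 had a 1.49-fold difference between its highest and lowest times, CT20 and CT0 (F test over all times of day, adjusted p = 0.00225). Rpl6 had a 1.37-fold difference between CT16 and CT12 (same test, adjusted p = 0.00304). Of 59 listed oxidative phosphorylation genes, of 94 annotated, 58 peaked from CT14 to CT22, with a mean at 17.0 h (R = 0.960, adjusted p = 0.00047), and 56 differed among times of day. Cox6c, a subunit of cytochrome c oxidase, differed by 1.58-fold and Ndufa9, of complex I, by 1.20-fold. No member of either list passed the cosine test, over the table or adjusted over the list alone. Members moved together (correlation estimated by camera 0.958 for ribosomal and 0.878 for respiratory genes). R thus cannot tell a rhythm from a fluctuation that the columns share.

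Genes that protect against oxidants shared this timing. All 10 listed members peaked between 16.5 h and 18.6 h (R = 0.985, adjusted p = 0.00047), among them the peroxidases Prdx5 (1.74-fold, adjusted p = 0.0033) and Gpx4 (1.49-fold, adjusted p = 0.0019), and 8 of the 10 differed among times of day. The 7 listed immediate early and cAMP-response genes peaked between 16.7 h and 20.8 h (R = 0.941, adjusted p = 0.0115), with Ier2 at 1.92-fold and Crem, a cAMP-responsive transcription factor, at 1.46-fold. Of these, 4 differed among times of day, and all 7 passed the cosine test adjusted over the list alone, with 0 over the table. Of the 10 cytosolic heat-shock genes, 7 differed among times of day (mean peak 16.4 h, R = 0.701, adjusted p = 0.0388, a call that ended with CT52 left out or on the second day alone), such as the chaperone Hspa8 at 1.21-fold.

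The endoplasmic reticulum folding list (11 genes, mean peak 17.5 h) and the cell cycle list (5 genes, mean peak 19.0 h) missed the threshold for a common peak, both with an adjusted p of 0.0548. These outcomes depended on the setting. In the same test both lists passed after rescaling (adjusted p = 0.0217 and 0.0292). On the second day alone the adjusted p was 0.105 for folding and 0.0146 for the cell cycle. In the folding list, Dnajb11, a folding co-chaperone, differed by 1.24-fold with a peak at 18.3 h, and Sel1l, of the degradation machinery, by 1.25-fold with a peak at 4.58 h. In the cell cycle list, Tyms and Birc5 differed by 1.38-fold and 1.45-fold. Islet hormones and granule proteins had 6 listed members (R = 0.638, adjusted p = 0.151). Chgb, a granule protein, differed by 2.08-fold between CT20 and CT0 (adjusted p = 0.0166), while Scg5 did not pass (1.27-fold, adjusted p = 0.0596).

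Channels and islet regulators had fitted peaks in the opposite window, from cosines that none of them passed over the table. All 7 listed genes of glucose sensing and ion channels, namely Itpr1, Itpr2, Atp2a2, Cacna1a, Cacna1c, Cacna1d and Slc2a2, had fitted peaks between 4.55 h and 7.17 h (R = 0.976, adjusted p = 0.00245) and differed among times of day. Their median level was highest at CT60 (CT12), 0.31 log2 units above the mean, and below the mean at CT56 and CT80 (CT8), -0.05 and -0.10. Members of this list are called channel genes below, though not all of them encode channels. Itpr1, a calcium release channel of the endoplasmic reticulum, differed by 1.75-fold between CT12 and CT20 (adjusted p = 0.00128). The 4 listed islet transcription factors Rfx6, Rfx3, Myt1 and Insm1 had fitted peaks between 5.64 h and 6.67 h, with the highest median level at CT60 too, and all differed among times of day, Rfx6 by 1.45-fold between CT12 and CT16 (adjusted p = 0.00062). The 6 listed genes near type 2 diabetes association signals had a mean peak at 5.78 h (R = 0.948, adjusted p = 0.0189), with Prox1 at 1.40-fold and Thada at 1.34-fold.

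**Figure D2:**
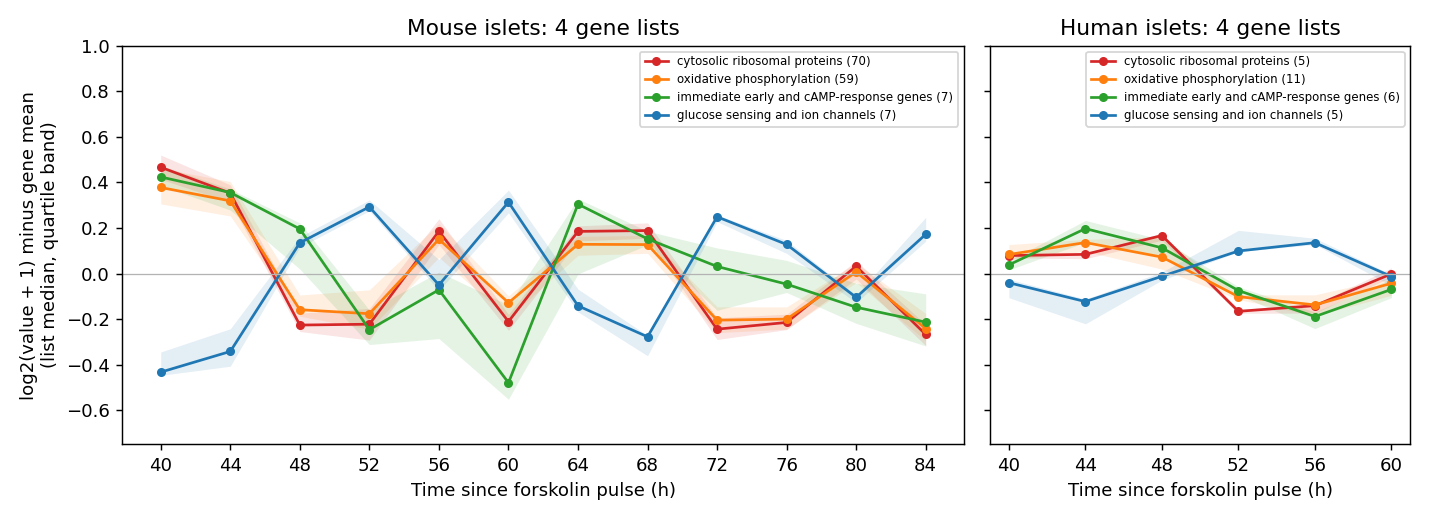
Median level of the listed members of 4 gene lists, as log2(value + 1) minus each gene's mean (vertical axis), against hours since the pulse (horizontal axis), with the number of members in parentheses and bands from the first to the third quartile of members. In the mouse, ribosomal and respiratory genes are highest at CT40 and CT44 and also lie above their mean at CT56, CT64, CT68 and, slightly, CT80, while channel genes run opposite.

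The exocytosis list was mixed. Of 10 members, 9 differed among times of day, and R was 0.360 (adjusted p = 0.357). The active-zone scaffold Rims2 differed by 1.37-fold with a peak at 6.34 h, and the membrane fusion protein Stx4a by 1.22-fold with a peak at 19.2 h. Receptors and cAMP signalling (5 members, adjusted p = 0.494) were mixed as well, with the incretin receptor Gipr at 4.54 h (1.84-fold) and the kinase subunit Prkar1a at 17.7 h (1.29-fold). Lists with fewer than 5 members had no test of timing. Cholesterol synthesis had Pmvk (1.69-fold, adjusted p = 0.00665) and Sc4mol (1.20-fold, adjusted p = 0.0721), and autophagy and lysosome had Lamp1 (1.09-fold, adjusted p = 0.225) among its 4.

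Markers of other cell types were few in the mouse table, and part of them had fitted peaks in the same window as the ribosomal genes, CT14 to CT22. Timp1 and Tagln, made by stellate cells and fibroblasts, differed by 4.41-fold and 3.75-fold with peaks at 19.8 h and 19.2 h (adjusted p = 0.0155 and 0.0125). Both were lowest at CT12, mainly through CT60 on day 1. Timp1 averaged 249 at CT60 and 851 at CT84, and Tagln 138 and 362. The ductal list had 6 members (R = 0.427, adjusted p = 0.357), among them the keratin Krt7, which differed by 1.38-fold with a peak at 19.4 h (adjusted p = 0.0202). The fitted peaks of Timp1, Tagln and Krt7 were later than the latest ribosomal one, 18.4 h, a difference that was not tested. The SE of the fitted peak was 1.40 h for Timp1 and 1.69 h for Tagln. Single members were listed for acinar (Amy1, peak 5.18 h), endothelial (Egfl7, peak 21.1 h) and leukocyte markers (Cd79a, peak 9.12 h), and none for Schwann cells.

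Among mouse genes past the time-of-day test, of at least middling level and with like timing on both days, the 10 largest amplitudes belonged to genes peaking from 17.3 h to 20.9 h. Il11, a cytokine, differed by 4.83-fold between CT16 and CT12 (adjusted p = 0.0226) and Ldha, which makes lactate, by 3.17-fold (adjusted p = 0.00979). The difference for Il11 was far larger on day 1, with 958 at CT40 and 76.3 at CT60, than on day 2, with 550 at CT64 and 292 at CT84. Fitted ranges had wide intervals, 1.84 to 8.58 for Il11 and 1.56 to 5.45 for Ldha. Timp1, Tpm2, Anxa2, Fam162a, Akr1b8, Ecm1 and Tagln were also in the group, each gene of it with an adjusted p above 0.15 in the cosine test. In the glycolysis and hypoxia list, Vegfa had a 1.26-fold difference and a peak at 4.20 h.

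Timing in the mouse table ran with gene structure. Across 3876 genes, the level at CT16 and CT20 minus that at CT4 and CT8 had a Spearman correlation of -0.506 with genomic span, -0.625 with transcript length and 0.347 with transcript GC (permutation p = 0.0001 each, the smallest that 10000 permutations give; adjusted p = 0.00012 over 7 relations; genes are not independent replicates). The fifth of genes with the shortest span (median 3.98 kb) had a median difference of 0.26 log2 units and the fifth with the longest span (median 151.6 kb) one of -0.22. The ribosomal and respiratory genes above had a median span of 4.26 kb, and the channel and exocytosis genes one of 205.9 kb. In the human table the correlation with the span of the mouse gene of the same symbol was -0.544 across 1469 genes. There CT16 and CT20 came before CT4 and CT8 in the only cycle sampled, so time of day was not separated from time in culture.

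**Figure D3:**
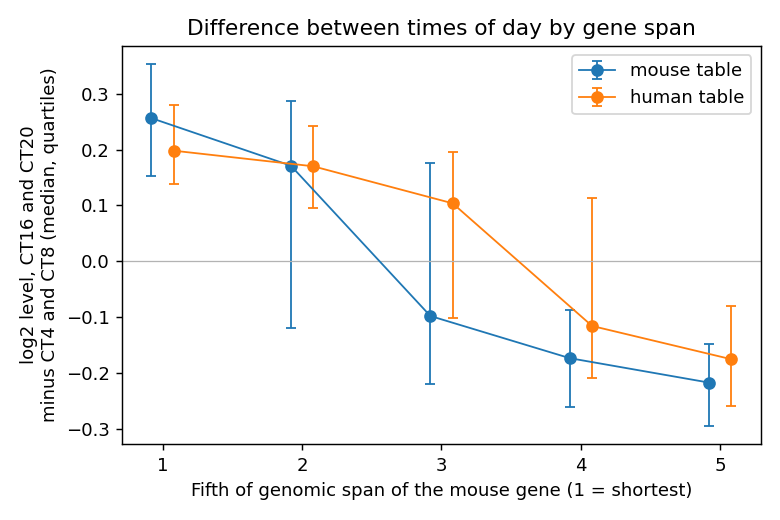
Median difference in log2 level between CT16 and CT20 on one side and CT4 and CT8 on the other (vertical axis) for listed genes binned by genomic span into 5 bins of equal size (horizontal axis), with bars from the first to the third quartile of genes. In both tables the shortest genes lie above 0 (0.26 and 0.20) and the longest below (-0.22 and -0.18).

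The second comparison asked whether levels and rhythms held from the first sampled day to the second. No gene differed in level between days at matched phase (limma, 0 of 3900 at adjusted p 0.05, 130 at an unadjusted p under 0.05). Among lists, oxidative phosphorylation lay lower on day 2 by a median of -0.13 log2 units, ribosomal proteins by -0.11, endoplasmic reticulum folding by -0.10, oxidative stress by -0.14 and islet hormones and granule proteins by -0.15 (camera with preset correlation, adjusted p = 7.42e-13, 1.45e-08, 1.51e-06, 0.00097 and 0.00184). None of these calls held with an estimated correlation (adjusted p = 0.626, 0.843, 0.333, 0.626 and 0.375).

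No gene passed the test for a different rhythm on the 2 days (interaction test in limma, 0 of 3900, 17 at an unadjusted p under 0.05). Amplitude was larger on day 1 in 2940 genes (75.4%), and the median log2 ratio of day 2 to day 1 was -0.50, which turned to 0.03 with CT80 left out. For Arntl the amplitude was 0.51 log2 units on day 1 and 0.41 on day 2, and for Nr1d1 0.54 and 0.35, with no difference by the interaction test (unadjusted p = 0.242 for Arntl and 0.0719 for Nr1d1).

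In human islets the same question was put to 1 cycle. Of the core clock, 5 genes were listed and 4 passed the cosine test, over the table and adjusted over the list alone. Both adjustments ran over genes already selected as cycling. By the authors' adjusted p, over all genes they tested, 0 of the 5 lay below 0.05. NR1D1 peaked at 14.5 ± 0.63 h (SE of the fit) with a 1.66-fold range (95% interval 1.38 to 2.00, adjusted p = 0.00625), and ARNTL at 7.92 ± 0.79 h with a 1.45-fold range (1.22 to 1.72, adjusted p = 0.0141). CRY1 peaked at 2.75 h (1.29-fold, adjusted p = 0.016) and CLOCK at 7.47 h (1.20-fold, adjusted p = 0.0225), while RORB did not pass (1.18-fold, adjusted p = 0.329). ARNTL averaged 513 at CT48 and 778 at CT56, and NR1D1 averaged 549 at CT40 and 312 at CT52.

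In the human series 747 of 1797 genes (41.6%) passed when adjusted over listed genes alone, with 1061 at an unadjusted p under 0.05. The authors' deposited table gives 34 genes with an adjusted p below 0.05, adjusted over all genes they tested, so the counts cannot be compared. The count of 747 fell to 45 with a linear trend in the model, to 46 without CT56, to 376 without CT52 and to 285 without the variance trend. Peaks fell from CT14 to CT22 in 799 genes (44.5%) and from CT2 to CT10 in 652 (36.3%).

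Human channel genes peaked from CT4 to CT10 and immediate early and respiratory genes from CT16 to CT22. All 5 listed genes of glucose sensing and ion channels passed, RYR2, CACNB2, CACNA1D, ITPR1 and G6PC2. Their mean peak was at 6.42 h (R = 0.955, adjusted p = 0.0491, a call that ended when CT44, CT52, CT56 or CT60 was left out). CACNA1D, a calcium channel subunit, had a 1.26-fold range and ITPR1 a 1.30-fold range. Of 6 immediate early and cAMP-response genes 5 passed, with a mean peak at 20.4 h (R = 0.992, adjusted p = 0.0078), such as IER2 (1.42-fold, adjusted p = 0.00548) and the phosphatase DUSP4 (1.30-fold, adjusted p = 0.00813). Of 11 oxidative phosphorylation genes 8 passed, with a mean peak at 19.6 h (R = 0.962, adjusted p = 0.0078), among them NDUFV1 at 1.31-fold (adjusted p = 0.00688) and UQCRC1 at 1.27-fold (adjusted p = 0.00938). By the authors' adjusted p, over all genes they tested, 0 of the channel genes, 1 immediate early gene and 1 respiratory gene lay below 0.05.

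The other lists differed in how many members passed. Of 5 ribosomal protein genes 3 passed, among them RPS19 at 18.8 h and RPL28 at 20.3 h, and all 5 passed when adjusted over the list alone. Of 9 exocytosis genes 4 passed, with RIMS2 peaking at 7.54 h and RAB3D at 20.5 h. TRIB3, a stress-induced pseudokinase, peaked at 19.8 h (1.39-fold, adjusted p = 0.00433), 1 of 4 folding-stress genes to pass. NEUROD1, an islet transcription factor, peaked at 7.88 h (1.20-fold, adjusted p = 0.0366). PDE3B peaked at 7.79 h and RGS2 at 11.8 h, and all 3 listed members of their list of receptors and cAMP signalling passed. MCM5 (21.1 h, 1 of 4 cell cycle genes past the threshold), SQSTM1 (20.3 h), GPX4 (18.4 h) and, near a diabetes association signal, KCNQ1 (21.3 h, where reads of its antisense transcript cannot be told apart without strand) passed as well. SCG3 and HSF1, the single listed members of the granule and heat-shock lists, did not, and the lists for cholesterol synthesis and glycolysis had no listed member.

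Markers of non-endocrine cells had some of the wider ranges in the human table. The acinar enzymes CTRB1 and CEL peaked at 21.6 h and 22.3 h with ranges of 1.99-fold (1.68 to 2.37) and 1.95-fold (1.57 to 2.42), and 4 of 5 acinar markers passed (adjusted p = 0.00172 for CTRB1). SYCN, a protein of acinar zymogen granules, peaked at 21.3 h with a 2.14-fold range. Of 6 ductal markers 5 passed, with KRT7 at 20.9 h (1.58-fold) and CLDN4 at 20.5 h (1.52-fold); their R of 0.652 did not pass the test against random lists (median R 0.349, adjusted p = 0.111). The matrix genes POSTN (1.95-fold) and DCN (1.56-fold) peaked at 9.79 h and 11.1 h. The leukocyte markers C1QA, TYROBP and PTPRC all passed, C1QA peaking at 11.6 h (1.69-fold) and PTPRC at 10.1 h (1.55-fold). The Schwann cell marker CDH19 peaked at 8.85 h (2.75-fold, 1.53 to 4.96, adjusted p = 0.0333), and the endothelial marker PLVAP did not pass. Among the other largest amplitudes, IGFBP3, INHBA, CD109 and CCDC80 peaked between 9.73 h and 11.7 h, and GDF15 and MUC6 at 20.96 h and 23.8 h.

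The last comparison set peak times in mouse and human islets side by side. Of the 480 genes listed in both tables, 410 (85.4%) peaked within 4 h of each other, against 41.9% when gene pairs were permuted (two-sided permutation p = 1e-05, the smallest that 100000 permutations give; across genes, which are not independent replicates). All shared genes entered, though only 2 passed the cosine test in both tables. The human fits rest on 1 cycle, where time of day follows the order of collection. Both series began 40 h after the pulse, so an early-to-late change in culture common to both could raise the share within 4 h. No fit with a trend was run for this share, so such a change was not told apart from a common daily timing. Human peaks were later by a circular mean of 0.55 h. Among clock genes the difference, human minus mouse, was 0.78 ± 0.83 h (SE) for NR1D1, 0.18 ± 1.31 h for CLOCK, 0.47 ± 1.05 h for CRY1 and 2.42 ± 0.91 h for ARNTL, none past the test of the difference (limma estimates, adjusted p = 0.778, 0.986, 0.919 and 0.255). RORB, which missed the threshold in both tables, had fitted peaks at 17.5 h in the mouse and 6.13 h in the human. The largest products of amplitude belonged to KRT17, CYP17A1, FST, NR1D1 and LGALS4, of which CYP17A1, FST and NR1D1 peaked within 4 h. Of the lists, all 5 shared ribosomal, all 5 shared respiratory and all 4 shared exocytosis genes peaked within 4 h. The tables were normalized separately, so levels were not compared.

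**Figure D4:**
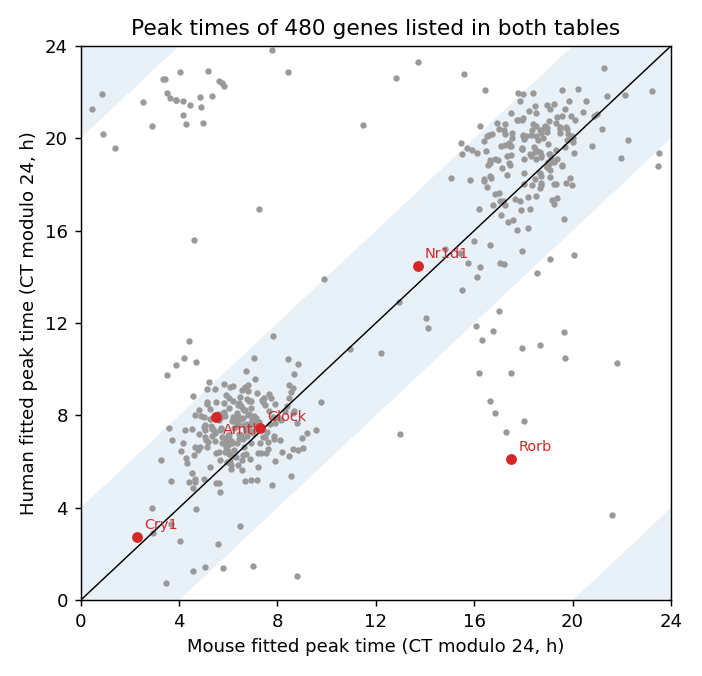
Fitted peak time in human islets (vertical axis, h) against that in mouse islets (horizontal axis, h) for the 480 genes listed in both tables, each point 1 gene, with shared clock genes in red, the line of equal times in black and a band of 4 h to either side. Of the genes, 410 lie within the band, in clusters near CT6 and near CT18, and Rorb lies outside it.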

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

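Fitted peak times of 3 genes differed between mouse and human islets in the test of the difference itself (limma estimates, adjusted p below 0.05 over 480 shared genes). Gcnt1 had fitted peaks at 17.3 h in the mouse and 7.29 h in the human, a difference of -10.0 h (adjusted p = 0.00484). Trim67 had fitted peaks at 21.8 h and 10.3 h, a difference of -11.5 h (adjusted p = 0.017), and Inpp5f at 18.0 h and 7.76 h, a difference of -10.2 h (adjusted p = 0.0175). None of the 3 passed the cosine test over the mouse table, where only clock genes did. Human peaks rest on 1 cycle, so these differences need not be reversals of a daily rhythm. In all, 41 shared genes had fitted peaks more than 6 h apart.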

How the results depend on the processing

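Omission of time points beyond the planned omission of the first, the tests without a variance trend, the 12 h cosine, the time-of-day count and the comparisons over all listed or shared genes were chosen after the data were seen. No paired analysis was possible because the columns are averages that carry no replicate number, so the planned replicate block and omission of replicates were not run, nor was the fit over single time points as a factor. The mouse cosine count of 4 stood at 3 or 4 under the pseudocounts, rescaling, a trend, day as a term, 22 h, no variance trend and without the first time point. It was 0 at 26 h and 0 with ranks, 3192 with a 12 h cosine and 3045 with times of day, and lay between 0 (CT64 or CT76 omitted) and 10 (CT60 omitted). The time-of-day count stayed between 2438 and 3302. The human count of 747 became 45 with a trend, 285 without a variance trend, and 46 (CT56 omitted) to 756 (CT48 omitted). It stayed within 1.5 times under the pseudocounts, the mean filter, rescaling, 22 h, 26 h and ranks. The mean filter removed no mouse gene and is no test there. Counts for the days stayed at 0 throughout, and the amplitude ratio of -0.50 ranged from -1.01 (CT56 omitted) to 0.035 (CT80 omitted), with -0.24 without CT40, -0.82 without CT60 and -0.16 without CT84. Human lists with a common peak numbered 3 of 4 by called members, 5 of 8 by all listed members and 2 or 3 with a time point omitted. Mouse lists numbered 7 of 14, and 6 to 9 otherwise. The share of shared genes within 4 h lay between 76.5% (CT60 omitted in both tables) and 95.3% (called genes alone). At adjusted p 0.01 in both tables no gene remained. Over settings of named genes, 151 ended a call, 2 made one and 1782 did neither, and none moved a peak by over 6 h. What made a count change with a setting was not tested. With averages alone, precision is limited by 12 and 6 values per gene, and depth is unknown.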

Other observations

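The tests on steady drift and on handling order, and the excess over random values, were chosen after the result was seen; the others were written before their result.

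Waveforms in the authors' deposited mouse table were steep on one side. An asymmetry of 4 h or 20 h was given to 3418 of 3905 mouse genes (87.5%) and to 600 of 1800 human genes (33.3%). Of the mouse genes, 1719 turned between CT20 and CT0 and 1502 between CT12 and CT16. The first principal component of the columns held 67.0% of the variance, and after its removal the share with such a template fell from 82.7% to 53.2%, or 64.3% of its size. The limit of 50% set for this test could hardly be reached, since random values alone gave 58.6%. Of the excess over random values none was left (-22.3% of it), as 1 shared component would give, but removal of that component also takes away a rhythm that the listed genes share, so the source cannot be told apart.

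Averaged over both days, mouse ribosomal and respiratory-chain genes were higher at CT16 and CT20 than at CT4 and CT8, by a median of 0.34 log2 units, and channel and exocytosis genes lower (-0.27), though the exocytosis list was mixed. A steady downward drift in culture would not give a later rise. Yet the first group was higher by 0.24 log2 units at CT64 and CT68 than at CT52, CT56 and CT60 (bootstrap interval over genes 0.20 to 0.25). This argues against such a drift only as far as the averages hold, since genes that move together do not measure the error of a time point. The rise came from CT52 and CT60, as the ribosomal median lay 0.19 above its mean at CT56, CT64 and CT68 alike. Bias with gene length, GC or level remains a candidate explanation: after a fit of these properties to the other listed genes, 18.9% of the difference was left (13.7 to 26.3), from 0.34 to 0.06 log2 units, and 10.2% of that of the channel and exocytosis genes (-16.7 to 85.9). A handling order repeated on both days cannot be told apart from a rhythm, as the difference was 0.40 on day 1 and 0.26 on day 2. A daily change in transcription of short and long genes, which the sampling times were meant to show, would give the same values and stays open.

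Long and short genes parted in human islets in the direction seen in mouse islets, as the hypothesis predicted (Spearman rho -0.544 across genes, permutation p = 0.0001, the smallest that 10000 permutations give). In the human series CT16 and CT20 are CT40 and CT44 alone, and CT4 and CT8 are CT52 and CT56 alone. A change from early to late in culture could give the same sign, so the test cannot tell it from a daily difference. Part of the common timing went with gene length, GC and level shared by both species, which does not show that these properties caused it. When human peak times were permuted only among genes of like properties, in 10 bins, 73.6% lay within 4 h on average and at most 78.1%, against 85.4% observed and 42.0% in free permutation. Of the excess over free permutation, 72.9% went with these properties as binned. Genes within 1 of the 10 bins still differ in them, so the test cannot decide whether they are the whole source of the common timing.

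Human acinar markers had a mean peak at 21.1 h, while the peaks of ductal markers were spread and listed stromal and leukocyte markers peaked between 9.79 h and 11.6 h. A change in the share of cell types over time could give this. Acinar markers would then share a common amplitude. The limma amplitudes of those listed ran from 0.34 to 0.53 log2 units without a detectable difference (chi-square test of heterogeneity, p = 0.0854), which excludes nothing with so few genes. A rhythm within these cells was not tested apart from it.

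Chance was examined by reordering columns. For the mouse cosine count of 4, 5 of 100 orders gave as many, and another order gave 1928, so chance cannot be excluded and orders that call many genes point to a structure of the columns. For the comparison of days and the interaction, where 0 genes were observed, every one of the 100 and 32 splits must give as many (highest other 1593 and 0), so these tests are void, although a split with 1593 genes again points to a structure of the columns. For the human count of 747 and the mouse time-of-day count of 3045, 1 of 60 and 1 of 100 orders, the real ones, gave as many (highest other 740 and 1762), but genes were chosen on the real order, so these say nothing about chance.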
